A study of Oryza sativa with 39 samples.

How the data were processed

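Rice plants were grown with 14 h of light at 30 °C and 10 h of dark at 25 °C, per the labels' protocols. Iron was left out of the hydroponic medium from day 27 for 7 days in some plants, and others received 10 µM cadmium (Cd) for 24 h from day 33. Per the labels, the root tip segment from 0.5 to 1.5 cm was sectioned at 10 to 20 µm and divided by laser microdissection, in which a laser isolates chosen cells from a tissue section, into vascular bundle (VB), cortex, and the outer layer of epidermis with exodermis (EP). At the lowest node of normal and Fe-deficient plants, the vascular bundle of a new leaf (newDC in the labels) and that of an old leaf (oldDC) were isolated in the same way. This gave 39 arrays in 13 groups of 3, assigned by label. The labels do not say whether the 3 samples of a group came from separate plants, so p-values measure the spread between these samples, which may be technical.

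Each sample was hybridised to a single-colour Agilent array of 45151 spots read on a G2505C scanner. Per the file headers, the authors extracted the spots with Feature Extraction 10.5.1.1 under protocol GE1_105_Dec08. The same headers give the deposited values as linear Cy3 intensity, background-adjusted and detrended, with low signals replaced by surrogates. No normalisation between arrays is given in the sources used here. The authors' deposited table held the same intensity as the scanner files for all 45151 spots of every array, so using it changed no value. The array pairs its probes with rice locus identifiers and older descriptions, and these names were kept. The rice gene table supplied (ASM3414082v1) holds no such identifiers, so no locus was joined to it and no coordinate is printed.

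Intensity was log2-transformed and scaled by subtracting each array's 75th percentile. Control spots and outlier spots were left out, and spots of the same probe were averaged. Of 41908 gene probes, the one with the highest mean over all arrays stood for each of 29695 genes, 7801 of which had several probes. Levels are log2 signal relative to that percentile and are not compared between probes. The number of arrays limits the precision, and no spot was saturated. The 75th percentile of intensity ranged from 92.4 on normal oldDC replicate 1 to 736 on Cd VB replicate 2. Between 46.7% and 67.1% of probes were well above background, against 0.0% to 4.58% of the 153 negative control spots. Pearson's r across genes between arrays of a group was 0.907 to 0.968 (genes are not independent replicates), and no pair of arrays was identical: the smallest mean absolute log2 difference was 0.431.

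A linear model with a mean for each of the 13 groups was fitted to all 39 arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table. A gene was tested where it was well above background on all 3 arrays of at least 1 group compared. It was called where the Benjamini-Hochberg adjusted p was under 0.05 and the change at least 2-fold. Values after ± in a change are the fit's standard error (SE) with n = 3 arrays per group, and in a level the SD of 3 arrays. The comparisons were Fe deficiency against normal in 5 tissues, Cd against normal in the 3 root tissues, and 4 comparisons between normal tissues. Interaction terms tested whether a treatment effect differed between tissues, in 7 cases. Where a gene was above background on no array of a group, and for every fold given with 1 or 2 of 3 arrays of its lower group above background, the text gives the change as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Log2 changes are fitted values, and where the text gives 1 or 2 of 3 arrays above background in the lower group their size is uncertain. Data were also simulated from the fitted group means with the fit's 1 SD per gene. There the fit recovered 22% of 2-fold, 84% of 4-fold and 98% of 16-fold changes for Fe deficiency in VB, with 5 false calls.

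These choices were made before the data were examined, as were the gene lists, from general knowledge: iron uptake and phytosiderophore synthesis, iron distribution and storage, iron regulators, the methionine cycle, zinc and cadmium transport and chelation, diterpenoid phytoalexins, nitrogen, phosphate and silicon uptake, metallothioneins, heat shock, glutathione S-transferases (GST), sulfate assimilation, jasmonate, class III peroxidases, aquaporins, photosynthesis, histones and DNA replication, cytosolic ribosomal proteins, phenylpropanoids and lignin, and markers of stele, endodermis, cortex and epidermis. The symbols were paired with loci from memory and checked only against the array's descriptions, so a symbol may name the wrong locus, and 4 list genes were not found on the array. After the data were opened, 1 gene was dropped from a list because the array describes its locus as another protein, 1 was matched to an older form of its identifier, and potassium channels were removed from the jasmonate list. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with adjustment over all 209 list tests, and again with an estimated correlation. Where members of a list were below background in 1 group, its median with them at the bound above is also given where it differs. Of the 71 list calls, 5 held with an estimated correlation: iron uptake and the methionine cycle in Fe-deficient VB and cortex, and iron distribution in Fe-deficient oldDC. The genes named are the members of these lists, the 5 called genes with a description that rose most and the 5 that fell most in each comparison, up to 10 genes called in the same direction in all 3 root tissues, and the 3 largest of each interaction. Ferritin genes OsFER1 and OsFER2, OsNAS1 and OsNAS2, TOM1 and Os12g0132500, and Os11g0115100 and Os12g0114800 are close copies of one another, so that a probe may read both members of a pair and their values are uncertain. Only the last pair shares a probe sequence.

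Replicate numbers from the labels paired the normal root samples: in VB, cortex and EP, same-numbered samples deviated together from their group means, with correlations across genes of 0.127 to 0.333 (VB and cortex), 0.219 to 0.267 (VB and EP) and 0.290 to 0.403 (EP and cortex). With the replicate number as a block, 6785, 9179 and 6708 genes were called in these 3 comparisons. The 39 arrays lay on 10 slides, most of which held more than 1 group, and slide was tried as a fixed block, as a random block and within slides. Other alternatives were normexp background correction (offset 50), quantile normalisation, a percentile over the 15106 probes above background on all arrays, no filter or a stricter filter on dim probes, a floor, a variance trend, the compared arrays alone, scan number as a block, other thresholds, other ways of combining probes, the fry list test, and each array left out in turn. One more, chosen after seeing the data, kept only the normal oldDC array with the most probes above background. Probes named for microRNAs were not used in the comparisons.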

Results

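Transcripts were measured on 45151-spot rice arrays in cell layers isolated by laser microdissection. Root tip vascular bundle (VB), cortex and epidermis with exodermis (EP) came from normal, Fe-deficient and Cd-treated plants. Vascular bundles of a new leaf (newDC) and an old leaf (oldDC) at the lowest node came from normal and Fe-deficient plants. Each of the 13 groups held 3 arrays. The comparisons asked which transcripts changed without iron or with Cd, and which distinguished the layers in normal plants. The share of probes well above background was 46.7%, 49.5% and 53.3% on the normal oldDC arrays, below the 55.6% to 60.1% of the Fe-deficient oldDC arrays.

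In the vascular bundle, iron uptake and phytosiderophore genes rose under Fe deficiency, and both ferritin genes fell. OsIMA1 (Os01g0647200), which encodes a small peptide of the iron deficiency response, rose at least 3026-fold (limma adjusted p = 4.4e-09). TOM1 (Os11g0134900), the exporter of deoxymugineic acid, rose at least 181-fold (adjusted p = 0.00071; above background on 2 of 3 normal arrays), and the metal transporter gene OsNRAMP1 (Os07g0258400) rose at least 86.4-fold (on 1 of 3). The ferritin genes OsFER1 (Os11g0106700) and OsFER2 (Os12g0106000), for iron storage proteins, changed by log2 values of -5.84 ± 1.06 and -6.05 ± 1.16, each above background on 2 of 3 Fe-deficient arrays. Of 16908 genes tested, 122 rose and 155 fell.

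Of 11 iron uptake and phytosiderophore genes tested in the vascular bundle, 9 rose and none fell, and 10 rose when adjusted over the list alone. The list rose (median 4.86, 4.85 with its dim members at their bound, camera adjusted p = 1.9e-25; 0.00599 with estimated correlation). The phytosiderophore synthesis genes OsNAS1 (Os03g0307300), OsNAAT1 (Os02g0306400area on the array) and OsDMAS1 (Os03g0237100) rose by 6.69 ± 1.67, 5.63 ± 1.50 and 4.70 ± 0.93. OsNAS1 and OsNAAT1 lost their call without any of 5 of the 6 arrays. OsYSL15 (Os02g0650300), which imports the Fe(III)-chelator complex, and OsIRT2 (Os03g0667300) rose at least 28.9-fold and 8.05-fold. The Fe(II) importer gene OsIRT1 (Os03g0667500) and the nicotianamine exporter gene ENA1 (Os11g0151500) rose by 3.83 ± 0.62 and 4.86 ± 0.72, ENA1 above background on 1 of 3 normal arrays. Of the 11 methionine cycle genes tested, 6 rose (9 adjusted over the list alone). OsIDI4 (Os09g0453800) rose by 3.81 ± 0.47, OsDEP (Os11g0484000) by 3.35 ± 0.57 and OsMTN (Os06g0112200) by 2.16 ± 0.41. That list rose (median 2.17, adjusted p = 2.6e-17; 0.0322 with estimated correlation). Of 9 iron regulators, 4 rose (4 adjusted over the list alone). They included the transcription factor genes OsIRO2 (Os01g0952800), at least 27.4-fold, and OsIRO3 (Os03g0379300), by 3.91 ± 0.49, and OsHRZ1 (Os01g0689300), which encodes an iron-binding ubiquitin ligase, by 1.38 ± 0.25. The regulators rose as a list (median 0.84, adjusted p = 1.1e-05; 0.0564 with estimated correlation).

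Of 15 iron distribution and storage genes in the vascular bundle, 4 rose and 3 fell (5 and 3 adjusted over the list alone). OsMIR (Os12g0282000) rose at least 33.9-fold, OsYSL2 (Os02g0649900), a nicotianamine-metal transporter gene, at least 4.09-fold, OsOPT7 (Os03g0751100) by 4.82 ± 0.60 and OsYSL9 (Os04g0542200) by 2.81 ± 0.41. OsVIT2 (Os09g0396900), for a vacuolar iron transporter, fell at least 17.4-fold beside both ferritin genes. The list rose (median 0.67, adjusted p = 0.00285; 0.125 with estimated correlation). Class III peroxidases fell as a list (median -0.23, adjusted p = 0.00128; 0.187 with estimated correlation): 6 of 59 fell and none rose (9 and 1 adjusted over the list alone), among them Os04g0689000 (-6.36 ± 1.16) and Os04g0688200 (-4.92 ± 0.76). Jasmonate genes fell as a list (median -0.69, adjusted p = 5.6e-06; 0.326 with estimated correlation), and 1 of 23 was called, the ZIM-domain gene Os03g0180900 (-4.93 ± 1.31; 1 adjusted over the list alone). The largest falls outside these lists were the oxalate oxidase gene Os08g0189300, at least 243-fold, and the nodulin-21 gene Os04g0538400, at least 75-fold. Among genes outside the iron lists, 2 metallothionein genes rose, Os11g0704500 (3.80 ± 0.61) and Os12g0568500 (3.35 ± 0.66), and a phenylalanine ammonia-lyase gene, Os02g0627100, fell by 4.61 on the log2 scale. On the Fe-deficient arrays Os04g0688200 was above background on 1 of 3, and Os04g0689000, Os03g0180900 and Os02g0627100 on 2 of 3. The cortex marker RCc3 (Os02g0662000) stood at -1.43 in this comparison and was called only when adjusted over its list alone. With slide as a block, and within the slide that held both groups (1 Fe-deficient and 3 normal arrays), 162 genes were called. Fitting only these arrays called 114, and requiring signal above background in both groups called 74.

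In the cortex Fe deficiency changed 2325 of 17200 genes tested, 1098 higher and 1227 lower. Each of the 11 iron uptake and phytosiderophore genes rose (11 adjusted over the list alone), with a median log2 change of 8.37 (8.03 with dim members at their bound). OsNAS1 rose by 12.57 ± 1.67, OsNAS2 (Os03g0307200), the other nicotianamine synthase gene, by 11.03 ± 1.74, OsNAAT1 by 11.84 ± 1.50 and OsNRAMP1 by 10.15 ± 0.79, and TOM1 rose at least 1239-fold. OsNAAT1 and OsNRAMP1 were above background on 1 of 3 normal arrays, and OsNAS2 was measured on 2 of 3 Fe-deficient arrays. OsNRAMP5 (Os07g0257200), the manganese and cadmium importer gene, rose least (1.99 ± 0.61, adjusted p = 0.0229) and lost its call without any of 4 of the 6 arrays. The list rose with an adjusted p of 1.1e-17, and the adjusted p = 0.0297 with an estimated correlation. OsYSL15, ENA1, OsIRO2 and OsMIR each passed from below background on all 3 normal arrays to at least 124-fold, 107-fold, 191-fold and 202-fold higher levels.

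Of 12 methionine cycle genes in the cortex, 9 rose (9 adjusted over the list alone), led by OsARD1 (Os03g0161800) with 7.21 ± 0.60, OsIDI4 with 6.30 ± 0.47 and OsFDH (Os06g0486800) with 5.33 ± 0.37. The list rose (median 4.34, adjusted p = 1.7e-14; 0.0322 with estimated correlation). Of 9 iron regulators, 5 rose and 1 fell (5 and 1 adjusted over the list alone): OsHRZ2 (Os05g0551000), a second ubiquitin ligase gene, rose by 5.42 ± 0.36 and OsHRZ1 by 3.76 ± 0.25, while the transcription factor gene OsbHLH059 (Os02g0116600) changed by -1.26 ± 0.15. The regulators rose as a list (median 3.76, adjusted p = 0.00107; 0.142 with estimated correlation). Of 15 distribution and storage genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone), among them OsNAS3 (Os07g0689600) with 5.37 ± 0.97, OsOPT7 with 5.70 ± 0.60, and OsFER1 and OsFER2 with -6.29 ± 1.06 and -6.35 ± 1.16, both above background on 1 of 3 Fe-deficient arrays. That list rose (median 0.59, adjusted p = 0.00385; 0.123 with estimated correlation). Of 14 zinc and cadmium transport genes, 5 rose (5 adjusted over the list alone), including OsHMA4 (Os02g0196600), for a copper pump, by 3.21 ± 0.32 (above background on 2 of 3 normal arrays) and the zinc importer gene OsZIP4 (Os08g0207500) by 2.29 ± 0.39 (list median 0.47, adjusted p = 0.0171; 0.337 with estimated correlation).

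In the Fe-deficient cortex, of 38 glutathione S-transferase genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with Os10g0368100 at least 64.1-fold higher and Os01g0353400 and Os01g0369700 higher by 4.67 ± 0.81 and 4.67 ± 0.78. The list rose (median 0.63, adjusted p = 0.000155; 0.278 with estimated correlation). Of 12 metallothionein genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), Os12g0570700 by 6.34 ± 1.21. Their list call (median 0.98, adjusted p = 0.0341; 0.523 with estimated correlation) was lost without Fe-deficient replicate 3 (adjusted p = 0.0515), normal replicate 1 (0.0904) or normal replicate 3 (0.13). Of 23 sulfate assimilation genes, 6 rose and 3 fell (6 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.11). The sulfate transporter gene Os04g0652400 rose by 5.18 ± 0.79, and the serine acetyltransferase genes Os03g0196600 and Os01g0720700 changed by 4.20 ± 0.76 and -3.89 ± 0.49. In their lower group Os03g0196600 was above background on 1 of 3 arrays and Os04g0652400 and Os01g0720700 on 2 of 3. Of 95 heat shock genes, 6 rose (5 adjusted over the list alone) and the list was not called (adjusted p = 0.533).

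Among genes that fell in the Fe-deficient cortex were 15 of 58 class III peroxidases, against 2 that rose (15 and 3 adjusted over the list alone), with Os10g0109300 at -9.06 ± 1.29 (above background on 2 of 3 Fe-deficient arrays) and Os04g0688100 at -5.94 ± 0.61. The peroxidase list call (median -0.49, adjusted p = 0.0218; 0.481 with estimated correlation) was lost without Fe-deficient replicate 1 (adjusted p = 0.0598), normal replicate 2 (0.0719) or normal replicate 3 (0.0627). The flavanone hydroxylase-like gene Os03g0122300 changed by -7.57 ± 0.59, the root-specific gene Os10g0552300 fell at least 52.8-fold, and Lsi1 (Os02g0745100), the silicon importer gene, changed by -4.30 ± 0.84. Of 21 photosynthesis genes, 8 fell and none rose (10 and 1 adjusted over the list alone), including Os07g0544800, at least 22.1-fold. Their list median was -1.07, or -0.50 with 5 dim members at their bound (adjusted p = 0.0253; 0.44 with estimated correlation). That call was lost without normal replicate 1 (adjusted p = 0.0604) or normal replicate 2 (0.0526), and the median turned to 0.19 where both groups had to be above background. OsFH1 (Os01g0897700) rose by 1.38 ± 0.45, a call lost without any of 3 of the 6 arrays. It was listed as an epidermis marker but did not mark EP in normal plants, where its level was -2.23 in EP, -1.87 in cortex and -0.855 in VB. The normal cortex arrays lay on 1 slide and the Fe-deficient ones on another, so slide and treatment cannot be told apart. Of 323 genes at least 32-fold brighter in normal vascular bundle and above background on no normal cortex array, 59, 24 and 62 were above background on Fe-deficient replicates 1, 2 and 3 (median change 0.25, 0.159 to 0.367). Replicate 3 stood apart, with a median of the histone and replication list of 2.351 against -0.315 and 0.545 and a first principal component of 75.2 against 107.8 and 109.1. Requiring signal above background in both groups called 1381 genes, and normexp 1509.

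In the epidermis and exodermis, Fe deficiency changed 1435 of 16584 genes, 743 higher and 692 lower. OsIMA1 rose at least 1489-fold, OsMIR at least 284-fold and OsIRT2 at least 182-fold, and outside the lists the ABA-induced membrane protein gene Os05g0381400 rose at least 242-fold. Both ferritin genes fell, OsFER1 at least 21.9-fold and OsFER2 at least 26.4-fold. Normexp gave 329 higher and 577 lower. The share of probes above background was 57.3% to 58.7% on the normal and 58.6% to 67.1% on the Fe-deficient arrays.

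Of 11 iron uptake and phytosiderophore genes in the epidermis and exodermis, 8 rose (9 adjusted over the list alone), OsNRAMP1 by 7.14 ± 0.79, OsDMAS1 by 4.26 ± 0.93 and TOM1 by 5.06 ± 1.45, the last not called without any of 4 of the 6 arrays. The list rose (median 4.05, adjusted p = 1.5e-08; 0.123 with estimated correlation). Of 11 methionine cycle genes, 8 rose (9 adjusted over the list alone), with OsIDI2 (Os11g0216900) at 5.51 ± 0.64, OsARD1 at 4.88 ± 0.60 and OsMTK1 (Os04g0669800) at 3.84 ± 0.50 (list median 3.84, adjusted p = 3.4e-14; 0.0564 with estimated correlation). Of 9 regulators, 5 rose and 1 fell (5 and 1 adjusted over the list alone): OsHRZ1 rose by 3.48 ± 0.25 and OsIRO2 by 5.47 ± 0.78, and OsbHLH058 (Os05g0455400), for a transcription factor, changed by -1.64 ± 0.24. OsNRAMP1 and OsIRO2 were above background on 2 of 3 normal arrays. The regulators rose as a list (median 2.17, adjusted p = 0.0097; 0.288 with estimated correlation). Of 16 distribution and storage genes, 4 rose and 2 fell (5 and 3 adjusted over the list alone), and their list call (median 0.76, adjusted p = 0.0221; 0.288 with estimated correlation) was lost without Fe-deficient replicate 2 (adjusted p = 0.0656).

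Class III peroxidases fell in the epidermis and exodermis (median -0.82, adjusted p = 0.000512; 0.313 with estimated correlation): 11 of 55 fell and 1 rose (12 and 2 adjusted over the list alone), among them Os01g0962700 by 5.30 on the log2 scale. Lsi2 (Os03g0107300), the silicon exporter gene, changed by -3.38 ± 0.59, the laccase gene Os01g0827300 by -5.20 ± 1.09, and the multicopper oxidase gene Os01g0127000 fell at least 70-fold. Cytosolic ribosomal protein genes rose as a list (median 0.54, adjusted p = 5e-08; 0.778 with estimated correlation), with 10 of 223 called higher (6 adjusted over the list alone). Of 86 heat shock genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone; list adjusted p = 0.18), with the 70-kDa heat shock protein gene Os03g0218500 at 2.24 ± 0.32. Os03g0218500 was above background on 1 of 3 normal arrays and Os01g0827300 on 2 of 3 Fe-deficient arrays. With slide as a block, and within the slide that held both groups (3 Fe-deficient arrays and 1 normal array), 923 genes were called. Fitting only these arrays called 546, and requiring signal above background in both groups 753.

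**Figure D1:**
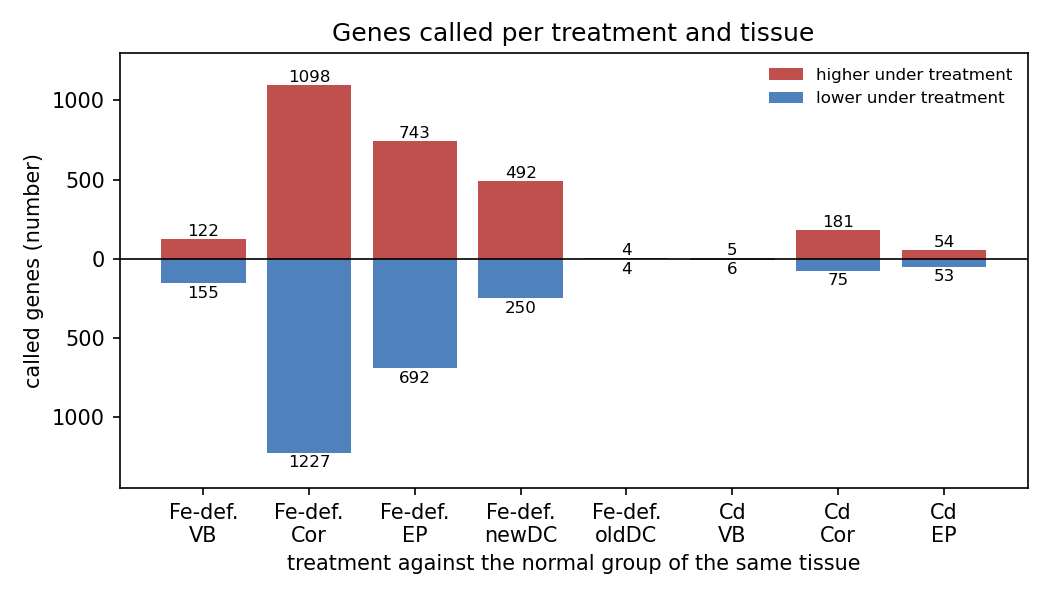
Bars give the number of genes called higher (upward) and lower (downward) in each treatment and tissue, from 3 arrays per group. Under Fe deficiency 2325 genes were called in the cortex and 8 in oldDC, and under Cd 256 in the cortex and 11 in the vascular bundle.

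**Figure D2:**
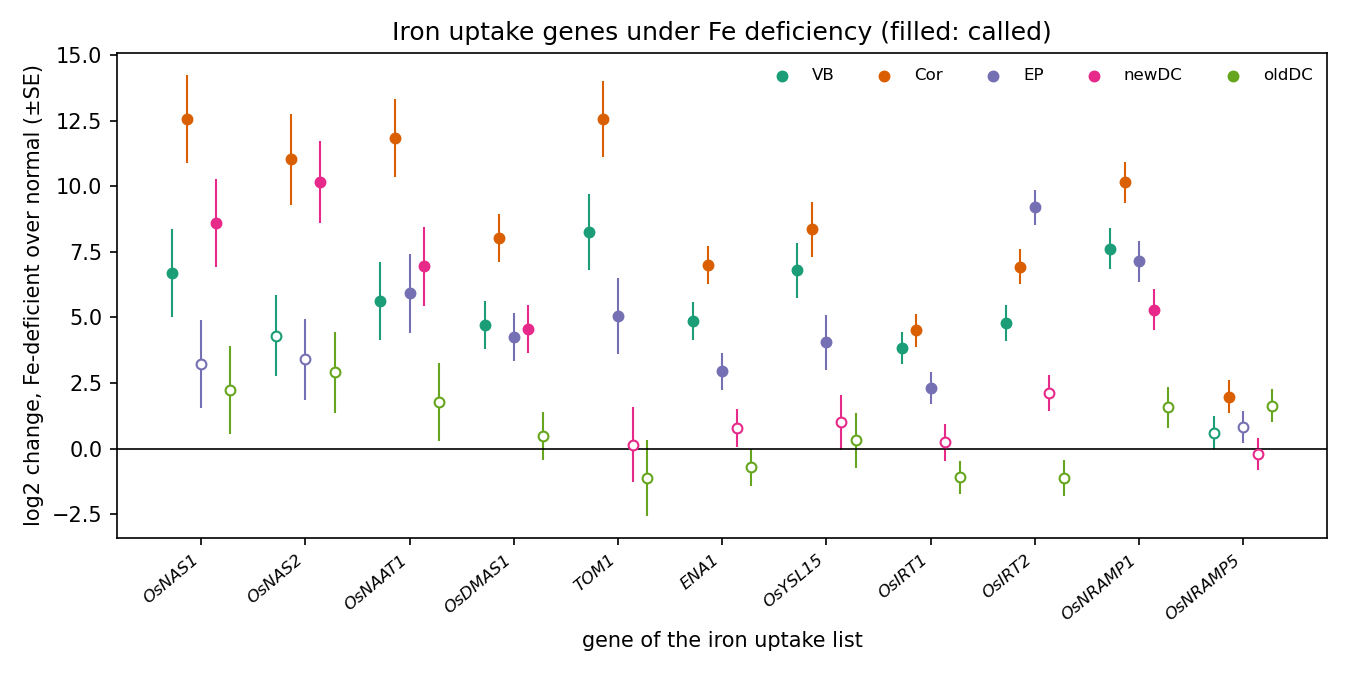
Each panel position shows the log2 change under Fe deficiency (± SE, n = 3 arrays per group) of the 11 iron uptake and phytosiderophore genes in 5 tissues, with filled symbols for called genes. All 11 were called in the cortex and the 5 tested in newDC. Where all normal arrays were below background the text gives an at-least fold.

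All 3 root tissues shared 74 rises and 51 falls under Fe deficiency and none under Cd. Cd-treated VB had 729 of 17655 genes at an unadjusted limma p under 0.05, not more than by chance. The shared rises included OsIMA1, OsMIR, TOM1, OsNRAMP1 and the acid phosphatase gene Os01g0191200, and the shared falls OsFER1, OsFER2, Os04g0689000 and the phospholipase D gene Os06g0604200 (-5.25 in VB, -6.38 in cortex, -5.66 in EP). Tests of the difference between tissues found 511 genes whose response differed between vascular bundle and cortex, 172 between vascular bundle and EP and 452 between EP and cortex. OsHRZ2 responded more in the cortex than in the vascular bundle (difference -4.57 ± 0.50) or EP (-3.25), and OsARD1 more in the cortex than in the vascular bundle (-5.11 ± 0.85). OsIRO2 and TOM1 responded less in EP than in the cortex (-4.33 and -7.51), but lost these calls without any of 7 and of 10 of the 12 arrays. OsIRT2 responded more in EP than in the vascular bundle (-4.41), a call lost without 1 of the 12 arrays. The normal levels of OsIRO2, TOM1 and OsIRT2 were below background in at least 1 of these tissues, so their fitted differences are uncertain. The count of 511 was 270 without Fe-deficient cortex replicate 1, 338 without normal cortex replicate 1, 329 without Fe-deficient VB replicate 3 and 330 without normal VB replicate 1. The count of 172 was 311 without normal EP replicate 1 and 52 with slide as a block, and the count of 452 was 297 without normal EP replicate 3.

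At the node, Fe deficiency changed 742 of 16770 genes in newDC, 492 higher and 250 lower. OsNAS2 rose at least 280-fold, OsNAS1 by 8.61 ± 1.67, OsNAAT1 by 6.95 ± 1.50, OsNRAMP1 by 5.30 ± 0.79 and OsDMAS1 at least 9.13-fold. All 5 iron uptake and phytosiderophore genes tested there rose (5 adjusted over the list alone; median 6.95, adjusted p = 1.9e-08; 0.0813 with estimated correlation). Histone and DNA replication genes fell: 15 of 49 fell and none rose (32 adjusted over the list alone), with histone H3.2 gene Os12g0415800 at -3.46 ± 0.93, histone H2A gene Os03g0162200 at -2.92 ± 0.66 and the DNA polymerase alpha subunit gene Os12g0242900 at -2.57 ± 0.68. In their lower group OsNAS1, OsNAAT1, Os12g0415800 and Os12g0242900 were above background on 1 of 3 arrays.

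The histone and replication list fell with a median of -1.56 (-1.53 with dim members at their bound, adjusted p = 6.2e-16; 0.288 with estimated correlation). Cytosolic ribosomal protein genes fell as a list (median -0.58, adjusted p = 6.4e-11; 0.74 with estimated correlation), with 0 of 239 called (0 adjusted over the list alone). Of 11 iron regulators, 4 rose (4 adjusted over the list alone): OsIMA1 by 7.91 ± 1.15, OsIRO3 by 2.68 ± 0.49, OsIRO2 at least 5.67-fold and OsIMA2 (Os07g0142100) at least 4.13-fold (list median 0.34, adjusted p = 0.00408; 0.229 with estimated correlation). OsVIT2 changed by -4.30 ± 0.68, and OsFER1 and OsFER2 by -3.90 ± 1.06 and -4.39 ± 1.16, both not called without any of 4 of the 6 arrays. The expansin gene Os04g0228400, for a cell wall loosening protein, rose by 7.85 ± 1.09 and the aquaporin gene Os09g0541000 changed by -3.22 ± 0.49. In their lower group OsVIT2 and Os04g0228400 were above background on 1 of 3 arrays and OsFER2 and Os09g0541000 on 2 of 3. Of 12 methionine cycle genes 0 were called (0 adjusted over the list alone; median 0.37, adjusted p = 0.199), and 7 of 99 heat shock genes rose (7 adjusted over the list alone; list adjusted p = 0.548). The count of 742 was 481, 1356 and 335 without Fe-deficient replicates 1, 2 and 3 and 415 without normal replicate 2. With slide as a block 394 genes were called, within the slide that held both groups (1 Fe-deficient and 3 normal arrays) 395, with only these arrays 79, with normexp 365, and with signal above background required in both groups 384.

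In oldDC, 8 of 15335 genes were called under Fe deficiency, 4 higher and 4 lower. OsIMA1 rose at least 685-fold (adjusted p = 1.2e-05) and Os04g0578600, a ferric reductase-like gene, at least 62.6-fold (adjusted p = 5.2e-10), each above background on 1 of 3 normal arrays. Os04g0538400 fell at least 39.3-fold and OsVIT2 at least 17.7-fold, and OsZIP7 (Os05g0198400), for a zinc transporter, changed by a log2 value of -2.17 ± 0.39 and was above background on 2 of 3 Fe-deficient arrays. The call of OsZIP7 was lost without Fe-deficient replicate 2 (adjusted p = 0.148) or normal replicate 1 (0.0539).

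Iron distribution and storage genes fell as a list in oldDC (median -0.24, adjusted p = 4.5e-05; 0.0317 with estimated correlation), with 1 of 14 called lower (4 adjusted over the list alone). Iron regulators rose (median 0.16, adjusted p = 0.000362; 0.0701 with estimated correlation), with OsIMA1 called of 9 tested (2 adjusted over the list alone). Only 1 iron uptake gene was bright enough to be tested there and it was not called (1 adjusted over the list alone), with a fitted change of 1.64. Without Fe-deficient replicate 1 or 3 the 8 calls became 13 and 15, and without normal replicate 1 or 2 they became 23 and 36. Without a filter on dim probes 1954 genes were called, and with only the normal array with the most probes above background, a setting chosen after seeing the data, 301. With slide as a block, and within the slide that held both groups (3 Fe-deficient arrays and 1 normal array), 29 were called, a floor gave 22, quantile normalisation gave 41 higher and 12 lower, and requiring signal above background in both groups called 0 (415 with an unadjusted p under 0.05, limma). The response differed between newDC and oldDC for 194 genes, among them OsIMA2 (difference 6.27) and OsIRO2 (4.62, lost without any of 8 of the 12 arrays), both below background in some of the groups. That count was 408 and 92 without Fe-deficient newDC replicates 2 and 3, 115 without normal newDC replicate 2, 123 without Fe-deficient oldDC replicate 2, 128 with slide as a block and 1547 without a filter on dim probes.

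**Figure D3:**
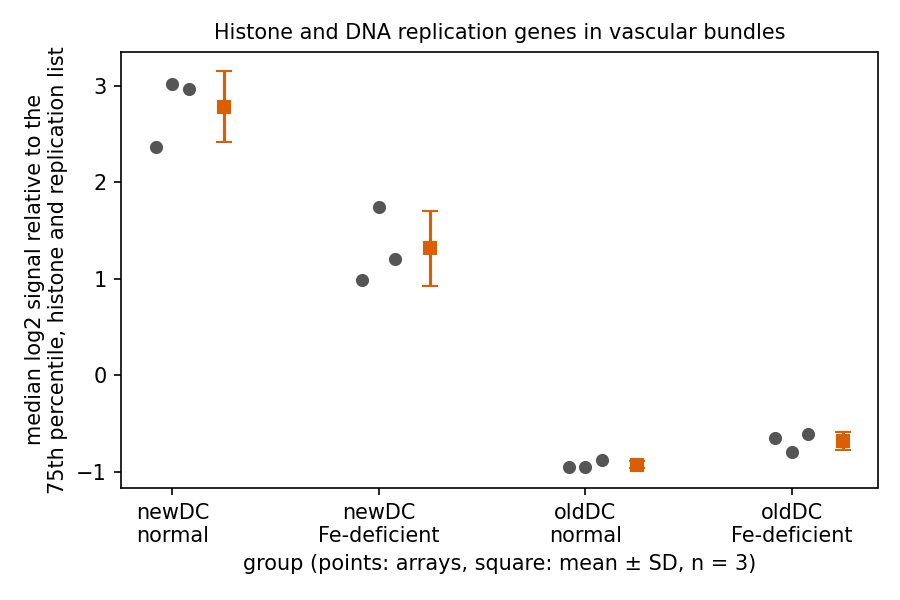
Points give the median log2 signal (relative to the 75th percentile of each array) of the histone and DNA replication list on each array of the newDC and oldDC groups, with the mean ± SD of 3 arrays. The medians were 2.361, 3.018 and 2.971 in normal and 0.989, 1.746 and 1.206 in Fe-deficient newDC, and -0.949, -0.952 and -0.881 in normal and -0.647, -0.792 and -0.613 in Fe-deficient oldDC.

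After 24 h of cadmium few genes were called in the vascular bundle: 11 of 17655, 5 higher and 6 lower. The multicopper oxidase gene Os03g0297900 rose by 5.46 ± 0.98 (adjusted p = 0.017) and the pathogenesis-related protein gene Os10g0191300 by 4.40 ± 0.73. The transcription factor gene Os05g0183100 (WRKY67) changed by -4.27 ± 0.60, the lysine decarboxylase-like gene Os09g0547500 by -4.28 ± 0.65 and the transferase gene Os09g0543900 by -4.26 ± 0.63. In their lower group Os03g0297900, Os05g0183100 and Os09g0543900 were above background on 1 of 3 arrays and Os09g0547500 on 2 of 3. Jasmonate genes fell as a list (median -0.90, adjusted p = 1.7e-12; 0.0955 with estimated correlation), with 0 of 23 called (5 lower when adjusted over the list alone). Iron uptake genes were not called as a list (median 0.07, 0 of 7 called, 0 adjusted over the list alone, adjusted p = 0.953), nor were zinc and cadmium transport genes (median 0.10, 0 of 15 called, 0 adjusted over the list alone, adjusted p = 0.955). Of the 10 genes chosen by the naming rule, 6 lost their call in at least 1 fit without an array. The count of 11 was 6 and 99 without Cd replicates 2 and 3, 64 and 22 without normal replicates 2 and 3, 4 with slide as a block, 37 with a floor and 27 without a filter on dim probes; normexp gave 2 higher and 1 lower.

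In the cortex, cadmium changed 256 of 17240 genes, 181 higher and 75 lower. The cinnamyl alcohol dehydrogenase gene Os09g0400400 rose at least 9.33-fold, the allyl alcohol dehydrogenase gene Os12g0227400 at least 5.08-fold, and the metallothionein gene Os01g0974200 by 4.34 ± 0.97. OsHMA4 rose by 1.23 ± 0.32 (above background on 2 of 3 normal arrays) and was the only zinc and cadmium transport gene of 14 called (1 adjusted over the list alone; list adjusted p = 0.68). Os01g0974200 and OsHMA4 were each at least 32-fold brighter in normal vascular bundle than in normal cortex. Stele tissue in the Cd-treated samples may therefore account for their rise, as may an induction by Cd. The bHLH gene Os04g0301500 fell at least 36.3-fold, the tryptophan decarboxylase gene Os08g0140500 changed by -4.47 ± 0.91 (above background on 1 of 3 Cd arrays) and the lipoxygenase gene Os04g0447100, of jasmonate synthesis, by -3.64 ± 0.81. Of 11 genes chosen by the naming rule, 9 lost their call in at least 1 fit without an array.

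Cytosolic ribosomal protein genes rose in the Cd-treated cortex (median 1.04, adjusted p = 2.8e-44; 0.323 with estimated correlation), with 9 of 237 called higher (133 adjusted over the list alone). Metallothioneins rose as a list (median 1.60, adjusted p = 0.00221; 0.288 with estimated correlation), 1 of 14 called (6 adjusted over the list alone). That list call was lost without Cd replicate 1 (adjusted p = 0.118). Jasmonate genes fell (median -0.98, adjusted p = 0.000125; 0.44 with estimated correlation), 1 of 26 called lower (2 adjusted over the list alone). Aquaporins had a median of -0.70 (adjusted p = 0.00649, lost without Cd replicate 2 at 0.114; 0.353 with estimated correlation), 0 of 8 called (0 adjusted over the list alone). Stele markers had a median of 1.28 (adjusted p = 0.0218, or 0.236 with estimated correlation), with 0 of 5 called (2 adjusted over the list alone). That call was lost without Cd replicate 1 (adjusted p = 0.19), Cd replicate 3 (0.0633), normal replicate 1 (0.0514) or normal replicate 2 (0.0766). OsPHO1;2 (Os02g0809800), a stele phosphate exporter gene, stood at -3.79 ± 1.65 in normal and -0.92 ± 0.82 in Cd-treated cortex, against 4.92 ± 0.15 in normal vascular bundle. The 3 Cd-treated arrays differed. Replicate 2 lay at 21.4 on the first principal component, against 89.4 and 94.4 for replicates 1 and 3. Its histone list median was 2.957 against 0.767 and 0.521. Replicate 1, on the slide of the Fe-deficient cortex arrays, had OsNAS1 at 7.95, against at most -0.292 on the others. OsNAS2, OsNAAT1, TOM1 (1.35 against at most -6.63), OsIMA1 (-0.19, -6.44), OsIRO2 and ENA1 were also higher, but not OsIRT1 or OsMIR. Of 93 heat shock genes 0 were called (1 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.743). The count of 256 was 67 and 1006 without Cd replicates 2 and 3 and 113 and 55 without normal replicates 1 and 3. No slide held both normal and Cd-treated cortex arrays, so slide and Cd cannot be told apart. The count was 564 with a floor, 392 with a variance trend, 164 with quantile normalisation, 128 without a filter on dim probes, 410 with slide as a random block, 41 with scan number as a block and 0 with only these arrays (1905 with an unadjusted p under 0.05, limma), and normexp gave 23 higher and 21 lower.

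In the epidermis and exodermis, cadmium changed 107 of 17380 genes, 54 higher and 53 lower. The Ole e 1 and extensin domain gene Os10g0546100 rose at least 32.7-fold, the GDSL lipase gene Os01g0216500 at least 23.5-fold, and the lipid transfer protein genes Os11g0115100 and Os12g0114800 at least 6.51-fold and 5.85-fold. The purple acid phosphatase gene Os12g0150700 changed by -4.76 ± 0.78 and the protein kinase gene Os04g0419900 by -3.16 ± 0.63, above background on 1 and 2 of 3 Cd arrays. Of 95 heat shock genes, 3 rose (3 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.682). Ribosomal protein genes rose as a list (median 0.65, 0.64 with dim members at their bound, adjusted p = 3.3e-21; 0.593 with estimated correlation) with 0 of 228 called (0 adjusted over the list alone). Jasmonate genes had a median of -0.62 (adjusted p = 0.00141; 0.59 with estimated correlation), 0 of 30 called (0 adjusted over the list alone), and this call was lost without Cd replicate 2 (adjusted p = 0.0961) or normal replicate 3 (0.0804). Diterpenoid phytoalexin genes were not called (median 0.40, 0 of 5 called, 0 adjusted over the list alone, adjusted p = 0.99). Probes above background were 63.5% to 64.8% on the Cd arrays and 57.3% to 58.7% on the normal arrays. Of the 323 vascular bundle genes dim in normal cortex, 144, 53 and 81 were above background on Cd replicates 1, 2 and 3. On normal arrays 56, 63 and 53 were, so Cd replicate 1 stood apart. The median change of the 323 was -0.327. Of 10 genes chosen by the naming rule, 6 lost their call in at least 1 fit without an array. The count of 107 was 59 and 177 without Cd replicates 1 and 3 and 166 and 62 without normal replicates 2 and 3. The Cd arrays had another slide and scan number than the normal ones, so neither can be told apart from Cd. The count was 671 without a filter on dim probes, 229 with a floor, 0 with only these arrays (1552 with an unadjusted p under 0.05, limma), 131 with slide as a random block, 5 with scan number as a block and 12 higher and 30 lower with normexp.

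The Cd response differed between vascular bundle and cortex for 2 genes, Os10g0113000 and Os12g0227400, and between vascular bundle and EP for 1, Os12g0259800. Between EP and cortex it differed for 5, including Os01g0902700 and Os04g0471100, the latter reversed to -0.249 with a floor. Leaving out 1 array moved these counts over 1 to 13, 0 to 52 and 0 to 40. Genes called in the same direction under Fe deficiency and Cd numbered 6 in the vascular bundle, all lower and including Os05g0183100 and Os09g0547500, 92 in the cortex (48 higher, 44 lower) and 38 in EP (21 higher, 17 lower). In EP, 2 genes were called in opposite directions, Os10g0455100 (1.34 under Fe deficiency, -2.25 under Cd) and the purple acid phosphatase gene Os11g0151700 (1.75 and -2.45). Independent lists of these sizes would share 0.0591, 11.7 and 3.31. Simulated unchanged groups against the same normal arrays shared 0, which cannot tell, since they hold no change to call. The covariance of the 2 changes was 0.201, 0.401 and 0.314, against simulated means of 0.105, 0.0885 and 0.103 and simulated maxima of 0.195, 0.164 and 0.158. The 3 normal arrays could not be split into groups of at least 2, so part of the excess may come from shared controls. Cortex Cd replicate 1, high in iron uptake genes, lay on the slide of the Fe-deficient arrays. The overlap in the vascular bundle was 39 and 18 without normal replicates 2 and 3 and 3 with slide as a block. In the cortex it was 28 and 260 without Cd replicates 2 and 3 and 60 and 33 without normal replicates 1 and 3. In EP it was 25 without Cd replicate 1 and 61 and 73 without normal replicates 1 and 2.

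Without a slide block, more genes were called between normal tissues than under any treatment. Normal tissues shared no slide, and for EP slide and tissue cannot be told apart. Between vascular bundle and cortex, 6773 of 18272 genes were called, 3657 higher in the vascular bundle and 3116 lower. Of 7 stele markers 6 were higher (6 adjusted over the list alone; median 3.65, adjusted p = 0.000992; 0.0642 with estimated correlation), with OsPHO1;2 at 8.71, the transcription factor gene OsSHR1 (Os07g0586900) at 5.72 ± 0.72 and OsCESA7 (Os10g0467800), a secondary wall cellulose synthase gene, at 4.11. The cortex marker RCc3 was lower by -6.73 ± 0.58 and the 1 endodermis marker tested, OsCASP1 (Os04g0684300), for the Casparian strip, was higher by 3.73 ± 1.01. OsFRDL1 (Os03g0216700), for a citrate exporter, was higher in the vascular bundle by 7.92 ± 0.87, OsHMA4 by 6.53 ± 0.32, and OsHMA2 (Os06g0700700), for a zinc and cadmium pump, at least 3.27-fold. In the cortex OsCASP1 was above background on 1 of 3 arrays and OsPHO1;2, OsSHR1 and OsHMA4 on 2 of 3.

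Of 15 zinc and cadmium genes 6 were higher and 4 lower in the vascular bundle than in the cortex (6 and 4 adjusted over the list alone; adjusted p = 0.524). The phytochelatin synthase gene OsPCS1 (Os05g0415200) was at least 10.7-fold higher and the zinc transporter gene OsZIP5 (Os05g0472700) lower by -1.88 ± 0.40. Of 73 class III peroxidases 26 were higher and 26 lower (26 and 27 adjusted over the list alone; adjusted p = 0.78). Metallothioneins were divided 6 and 6 of 14 (6 and 6 adjusted over the list alone; adjusted p = 0.904), with Os01g0974200 1450-fold higher. Silicon genes parted, with Lsi1 at -3.42 and Lsi2 at 3.74. Ribosomal protein genes were higher as a list (114 of 238, 3 lower, 117 and 3 adjusted over the list alone; median 0.997, 0.992 with dim members at their bound, adjusted p = 5e-09; 0.751 with estimated correlation). With slide as a block 1599 genes were called, and requiring signal above background in both tissues 4029.

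Between vascular bundle and EP, 9160 of 18469 genes were called, 5165 higher in the vascular bundle and 3995 lower. Nutrient uptake genes were brighter in EP: 8 of 9 nitrogen, phosphate and silicon uptake genes were lower in the vascular bundle (8 adjusted over the list alone). Among them were the ammonium transporter gene OsAMT1;3 (Os02g0620600), at least 70.1-fold, the nitrate transporter gene OsNRT2.1 (Os02g0112100), at least 28.4-fold, and its partner gene OsNAR2.1 (Os02g0595900), by -8.91 ± 0.79. OsYSL15 was at least 232-fold and OsZIP1 (Os01g0972200), for a zinc transporter, at least 172-fold lower, while OsPHO1;2 was at least 300-fold higher (above background on 2 of 3 EP arrays) and OsSHR1 at least 35.2-fold higher.

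The nitrogen, phosphate and silicon list had a median of -5.07 between vascular bundle and EP (-4.83 with dim members at their bound, adjusted p = 0.00129; 0.0955 with estimated correlation). Iron uptake genes had a median of -2.93 (6 of 9 lower, 6 adjusted over the list alone; adjusted p = 0.0171, lost without normal EP replicate 1 at 0.0502; 0.63 with estimated correlation). Ribosomal protein genes were higher in the vascular bundle (221 of 238, 223 adjusted over the list alone; median 2.59, 2.56 at the bound, adjusted p = 7.1e-26; 0.523 with estimated correlation). Histone and replication genes were higher too (32 of 48, 32 adjusted over the list alone; median 2.096, 1.695 at the bound, adjusted p = 0.00691; 0.778 with estimated correlation). Phenylpropanoid and lignin genes were lower (22 of 40, 7 higher, 24 and 7 adjusted over the list alone; median -1.92, -1.70 at the bound, adjusted p = 0.00553; 0.641 with estimated correlation). So were the secondary wall genes OsCESA4 (Os01g0750300), OsCESA7 and OsCESA9 (Os09g0422500) of the stele list, by -2.78, -2.60 and -2.80 (OsCESA9 above background on 2 of 3 VB arrays). Stele markers were divided 4 higher and 4 lower of 8 (4 and 4 adjusted over the list alone; adjusted p = 0.98). Normexp gave 2748 higher and 3255 lower and moved the median of all genes by -0.22, and a percentile over probes above background on all arrays moved it by -0.13.

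Between EP and cortex, 6666 of 17767 genes were called, 2913 higher in EP and 3753 lower. All 9 iron uptake genes tested were higher in EP (9 adjusted over the list alone), OsNAS1 by 9.10 ± 1.67, OsNRAMP5 by 4.97 ± 0.61, OsIRT1 by 4.33, OsYSL15 at least 252-fold and TOM1 at least 19.8-fold. All 4 diterpenoid phytoalexin genes tested were higher (4 adjusted over the list alone) and, dim in cortex, could not have been lower. The momilactone genes CYP99A3 (Os04g0178400) and OsMAS (Os04g0179200) and the transcription factor gene DPF (Os01g0196300) were at least 87.4-fold, 13.6-fold and 5.46-fold higher. The cortex marker RCc3 was lower by -4.83 ± 0.58, and OsCSLD1 (Os10g0578200), a root hair gene and 1 of 2 epidermis markers, was at least 3.89-fold higher (1 adjusted over the list alone). The other, OsFH1, was not called (-0.35 ± 0.45, adjusted p = 0.533).

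The iron uptake list had a median of 5.32 between EP and cortex (4.97 with dim members at their bound, adjusted p = 3.5e-05; 0.288 with estimated correlation). Metallothioneins had a median of 3.01 (8 of 12 higher, 8 adjusted over the list alone; adjusted p = 5.2e-05; 0.125 with estimated correlation), and nitrogen, phosphate and silicon uptake genes 5.85 (3.68 at the bound, 5 of 9 higher and 1 lower, 5 and 1 adjusted over the list alone; adjusted p = 0.00468; 0.14 with estimated correlation). Phenylpropanoid and lignin genes were higher (19 of 34, 3 lower, 20 and 3 adjusted over the list alone; median 2.097, adjusted p = 1.7e-05; 0.384 with estimated correlation), with the laccase gene Os01g0827300 at 7.99 ± 1.09 (above background on 1 of 3 cortex arrays), and OsCESA4 of the stele list at 6.42 ± 0.51. Aquaporins were lower in EP (7 of 8, 1 higher, 7 and 1 adjusted over the list alone; median -2.72, adjusted p = 0.0169; 0.44 with estimated correlation). Ribosomal protein genes were lower as well (206 of 233, 207 adjusted over the list alone; median -1.59, -1.57 at the bound, adjusted p = 2e-18; 0.63 with estimated correlation). Normexp reversed the balance to 2313 higher and 1722 lower and moved the median of all genes by 0.22, and the other percentile moved it by 0.14. Requiring signal above background in both tissues called 3961 genes.

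At the node, 5410 of 16773 genes differed between newDC and oldDC, 3170 higher in newDC and 2240 lower. Histone and DNA replication genes were higher in newDC, 36 of 49 and none lower (36 adjusted over the list alone), with histone H2A gene Os01g0502700 at 9.08 ± 0.82 and histone H4 gene Os04g0583600 at 7.98. The sucrose transporter gene OsSUT1 (Os03g0170900), for phloem loading, was lower by -7.07 ± 0.76, a catalase gene, Os02g0115700, at least 1751-fold lower, and OsNAS3 lower by -3.67. OsMTP9 (Os01g0130000), for a manganese transporter, was lower by -4.12 and CAL1 (Os02g0629800), for a cadmium-binding peptide, higher by 6.33 ± 1.50. In oldDC Os01g0502700 was above background on 1 of 3 arrays and CAL1 on 2 of 3.

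The histone and replication list had a median of 2.60 between newDC and oldDC (2.098 with dim members at their bound, adjusted p = 8.4e-13; 0.337 with estimated correlation). The ribosomal protein list had 0.76 (0.75 at the bound, 69 of 239 higher and 1 lower, 67 and 1 adjusted over the list alone; adjusted p = 0.000178; 0.846 with estimated correlation). Class III peroxidases were lower (20 of 42, 4 higher, 20 and 4 adjusted over the list alone; median -1.20, adjusted p = 0.00095; 0.142 with estimated correlation). So were metallothioneins (5 of 8, 5 adjusted over the list alone; median -4.68, -3.90 at the bound, adjusted p = 0.000308; 0.118 with estimated correlation) and jasmonate genes (8 of 20, 8 adjusted over the list alone; median -1.42, adjusted p = 0.0103; 0.67 with estimated correlation). Of 26 sulfate assimilation genes 3 were higher and 9 lower (3 and 9 adjusted over the list alone; adjusted p = 0.0594). With slide as a block 3058 genes were called and without a filter on dim probes 11050, normexp gave 1410 higher and 1671 lower, and it moved the median of all genes by -0.26.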

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

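The test of stele-specific genes, the tests of the other genes called higher (the predicted change and the share needed), the test of old-leaf share, the test of differences among the normal oldDC arrays, the comparison of 99th percentiles between oldDC and newDC, and the setting with only the normal oldDC array with the most probes above background were chosen or changed after the results were seen. The first form of the old-leaf test, the median change of genes bright in oldDC and dim in normal newDC, had given 1.25 (0.942 to 1.66), toward that explanation, before it was replaced by the share those genes stand for.

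Tests of the difference between tissues set apart the following results. The Fe response differed between vascular bundle and cortex for 511 genes, the largest being Os02g0791300 (-8.51), Os12g0570300 (-8.30) and Os01g0191200 (-8.08). Between vascular bundle and EP it differed for 172 genes, led by Os03g0664400 (9.85, a call lost without any of 8 of the 12 arrays), Os07g0142300 (9.67) and Os01g0198500 (8.45). Between EP and cortex it differed for 452 genes, led by OsNAS1 (-9.35, lost without any of 7 arrays), Os10g0368100 (-9.23) and Os12g0132500 (-8.57). The Cd response differed between vascular bundle and cortex for 2 genes, Os10g0113000 (-5.86) and Os12g0227400 (-5.02), between vascular bundle and EP for 1 gene, Os12g0259800 (-4.11), and between EP and cortex for 5 genes, led by Os01g0902700 (-6.24), Os01g0850800 (-2.85) and Os04g0471100 (2.48, but -0.249 with a floor). The Fe response differed between newDC and oldDC for 194 genes, led by Os04g0228400 (7.83), Os02g0531600 (6.92) and Os04g0411400 (6.54). Of the genes named here, only OsNAS1, Os02g0791300, Os01g0191200 and Os04g0228400 were above background on at least 1 array of every group involved. For the others the size and rank of the difference are uncertain, since at least 1 group had no array above background. In data not used in the comparisons, 13 of 510 probes named for microRNAs were well above background on all 39 arrays.

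For each difference 50 splits of the arrays, the real one and 49 random, were fitted. For the 3 Fe differences between root tissues, 6, 9 and 9 of 50 splits gave as many genes as the real one, with highest other counts of 1279, 759 and 2068, and for newDC and oldDC 4 of 50, with 446. All the other splits among these left the arrays of 1 tissue unmixed, so they kept a real treatment effect. For the 3 Cd differences (vascular bundle and cortex, vascular bundle and EP, EP and cortex) 21, 31 and 24 of 50 splits gave as many, with highest other counts of 17, 54 and 593, so these counts of 2, 1 and 5 may be due to which arrays fell together.

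With 3 arrays per group there are 10 splits, too few for a share under 0.1. As many genes were called in 1 split of 10, the real one, for Fe deficiency in the vascular bundle (277, highest other 8), cortex (2325, 10), EP (1435, 27) and newDC (742, 21), and for Cd in the cortex (256, 20). The same held between normal tissues, for vascular bundle and cortex (6773, 25), vascular bundle and EP (9160, 82), EP and cortex (6666, 117), and newDC and oldDC (5410, 8). It was 5 of 10 for Fe deficiency in oldDC (8, highest other 137), 2 of 10 for Cd in the vascular bundle (11, 16) and 2 of 10 for Cd in EP (107, 210). In splits parting all 3 replicate numbers, the highest other counts between normal root tissues were 1, 1 and 2. For the gene lists, 1 of 50 splits gave as many calls as the real 71, the highest other being 69 and the median of the others 51, so most of that number also arises when arrays are mixed.

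In the Cd-treated cortex, the 323 vascular bundle genes dim in normal cortex had a median change of 1.108 (0.961 to 1.34). Under Fe deficiency, with the same normal arrays, it was 0.25. Of the genes called higher, 87.3% were also called higher in VB than in cortex, a share the common normal arrays may inflate. Stele tissue may account for the rise of stele-specific genes, as may induction by Cd. For the 140 other genes called higher, the share of 1.12% read from these dim genes predicts a median of 0.04508 (0.0266 to 0.0834) against 1.51 observed. Vascular tissue with the profile measured here would have to make up 66.2% of the samples (median over genes) and bring the stele-specific genes to -0.847, while they stood at -5.66 to -5, and 40 of the 140 are reached by no share, so such tissue does not account for these genes as a set, and cells with another profile were not tested. For the genes called lower, cortex-specific genes changed by a median of -0.3893 (-0.476 to -0.304), against -2.42 observed, so dilution does not reach them either. Scan number left the changes at 0.9724 (0.962 to 0.995) of their size while the standard errors grew 1.13-fold and 41 genes were called, so it does not account for the changes.

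The fall of histone and DNA replication genes in Fe-deficient newDC may reflect fewer dividing cells, which was not measured, or a difference in sampling. Old-leaf tissue would have to make up 79.1% of the samples to give it, and genes bright in oldDC and dim in normal newDC stand for 1.844% (132 genes). Within the slide that holds both groups the list median was -2.167 (-2.64 to -1.37), with 46 of 49 members below 0, but that slide holds 1 Fe-deficient array against 3 normal ones. A single array cannot tell, so the bound set for this test was too weak and slide stays open. Under quantile normalisation it was -1.643 (-2.15 to -1.17), with 47 of 49 below 0, so uneven brightness does not account for it.

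Fewer genes were called under Fe deficiency in oldDC than in newDC, which may be a weaker response. The order depends on the filter: without one on dim probes 1954 genes were called in oldDC and 706 in newDC, against 8 and 742, and with only the normal oldDC array with the most probes above background 301 were called in oldDC. The comparisons below concern the filtered genes. Recovery of simulated 2, 4, 8 and 16-fold changes was 30%, 68%, 96% and 98% in oldDC and 26%, 70%, 94% and 98% in newDC. All groups shared 1 SD per gene, so this cannot compare power. Among 11587 genes above background on all 12 arrays the ratio of calls was 0.00295 (1 against 339), so dim normal oldDC arrays do not account for it. The median SD between arrays of a group was 1.102 times as large in oldDC over both groups (0.253 against 0.229), but 1.40 times for the normal arrays (0.275 against 0.197) and 0.879 times for the Fe-deficient ones (0.230 against 0.261). The fit gives each gene 1 SD for all groups, so a wider spread in oldDC would widen its changes. The 99th percentile of their absolute log2 size was smaller there, 1.09 (1.04 to 1.18) against 1.998 (1.93 to 2.12), so a wider spread does not account for it. With 1 normal array kept, 287 to 383 genes were called in oldDC and 298 to 648 in newDC, and the ratio of genes called with each of the 3 was 0.04938, which cannot tell, because the error of a lone array enters in full.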

How the results depend on the processing

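The setting with only the normal oldDC array with the most probes above background was chosen after seeing the data. For the 420 named gene results, 7629 of 8559 values under other settings kept direction and call, 926 were weaker and 4 reversed. For the 71 list calls, 1369 of 1559 kept them, 186 were weaker and 4 reversed. With an estimated correlation 5 remained. Causes, and unadjusted counts against chance, were not tested except where stated.

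Requiring signal above background in both groups tests fewer genes, by construction. For Fe deficiency it called 74 (VB), 1381 (cortex), 753 (EP), 384 (newDC) and 0 (oldDC, 415 with an unadjusted p under 0.05 in limma) genes, for Cd 1 (VB), 44 (cortex) and 34 (EP), and between normal tissues 4029 (VB and cortex), 4890 (VB and EP), 3961 (EP and cortex) and 2804 (newDC and oldDC). The Fe response then differed for 166 (VB and cortex), 26 (VB and EP), 157 (EP and cortex) and 35 (newDC and oldDC) genes. The Cd response differed for 0, 0 and 0 (717, 308 and 641 with an unadjusted p under 0.05 in limma; VB and cortex, VB and EP, EP and cortex, the order kept below). Shared Fe and Cd genes were 0 (VB), 22 (cortex) and 14 (EP).

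Fitting only the arrays compared leaves fewer degrees of freedom. Counts were 114 (Fe, VB), 546 (Fe, EP), 79 (Fe, newDC), 4 (Fe, oldDC), 5 (Cd, VB), 0 (Cd, cortex; 1905 unadjusted, limma) and 0 (Cd, EP; 1552 unadjusted, limma). The Fe response differed for 236 genes between EP and cortex and 37 between newDC and oldDC. The Cd response differed for 0, 0 and 2 (1031 and 904 unadjusted for the first 2, limma). Shared genes were 0 in cortex and 0 in EP, since no gene was called there under Cd.

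Slide as a fixed block gave 162 (Fe, VB), 923 (Fe, EP), 394 (Fe, newDC), 29 (Fe, oldDC), 4 (Cd, VB), 1599 (VB and cortex), 3058 (newDC and oldDC), 52 (Fe difference, VB and EP), 128 (Fe difference, newDC and oldDC) and 3 shared genes (VB). Within 1 slide the Fe counts were 162 (VB), 923 (EP), 395 (newDC) and 29 (oldDC). As a random block, slide gave 410 (Cd, cortex) and 11 (Cd difference, EP and cortex). Scan number as a block gave 41 (Cd, cortex), 5 (Cd, EP), 0 (Cd difference, VB and cortex; 914 unadjusted, limma), 0 (Cd difference, EP and cortex; 905 unadjusted, limma), and 22 (cortex) and 2 (EP) shared genes. Replicate number as a block gave 301, 2370, 1457, 756 and 8 genes under Fe deficiency in VB, cortex, EP, newDC and oldDC, 10, 210 and 95 under Cd in VB, cortex and EP, and 5427 between newDC and oldDC.

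An adjusted p under 0.01 gave 1535 (Fe, cortex), 857 (Fe, EP), 359 (Fe, newDC), 5 (Fe, oldDC), 5 (Cd, VB), 17 (Cd, cortex) and 25 (Cd, EP), Fe differences of 184, 66, 153 and 64 (newDC and oldDC), and Cd differences of 1 (VB and cortex) and 0 (EP and cortex; 1188 unadjusted, limma). Without a minimum fold, 1133 genes were called in Fe-deficient newDC. Every probe on its own gave 3523 (Fe, cortex), 2159 (Fe, EP), 1343 (Fe, newDC), 24 (Fe, oldDC), 435 (Cd, cortex), Fe differences of 807 (VB and cortex), 270 (VB and EP) and 428 (newDC and oldDC), and a Cd difference of 4 (VB and cortex). The mean of probes gave 4 for that last difference.

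Normexp gave 1509 (Fe, cortex), 906 (Fe, EP), 365 (Fe, newDC), 3 (Cd, VB), 44 (Cd, cortex), 42 (Cd, EP), 4384 (VB and cortex), 6003 (VB and EP), 4035 (EP and cortex) and 3081 (newDC and oldDC). Fe differences were 340 (VB and cortex) and 24 (newDC and oldDC), Cd differences 0 (951 unadjusted, limma), 5 and 0 (820 unadjusted, limma), and shared genes 1 (VB), 21 (cortex) and 12 (EP). A floor gave 22 (Fe, oldDC), 37 (Cd, VB), 564 (Cd, cortex) and 229 (Cd, EP), Fe differences of 773, 370, 712 and 293, Cd differences of 4, 22 and 75, and 20, 204 and 101 shared genes in VB, cortex and EP. No filter on dim probes gave 1954 (Fe, oldDC), 27 (Cd, VB), 128 (Cd, cortex), 671 (Cd, EP), 11050 (newDC and oldDC), 1547 (Fe difference, newDC and oldDC), 2 (Cd difference, VB and EP), and 15, 59 and 117 shared genes. Quantile normalisation gave 53 (Fe, oldDC), 164 (Cd, cortex), 347 (Fe difference, newDC and oldDC) and Cd differences of 4 (VB and EP) and 3 (EP and cortex). A variance trend gave 16 (Fe, oldDC), 392 (Cd, cortex) and 2 (Cd difference, EP and cortex). Only the normal oldDC array with the most probes above background gave 301 (Fe, oldDC) and 347 (Fe difference, newDC and oldDC).

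Reversed values were -0.322 for Os04g0629700 in Fe-deficient oldDC (floor), -0.304 (floor) and -0.192 (normexp) for OsSHR2 between newDC and oldDC, and -0.249 for the Cd difference of Os04g0471100 between EP and cortex (floor). For lists they were 0.188 for photosynthesis (Fe, cortex; both groups above background), -0.0339 for ribosomal proteins (Fe, cortex; without Fe-deficient replicate 3), 0.0220 for histones (Cd, cortex; without Cd replicate 2, where the test pointed down) and -0.208 for photosynthesis (Cd, EP; no filter).

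With 1 array left out, the lone arrays of a group being assumed to vary like the others, Fe counts ranged over 218 to 308 (VB), 1791 to 2265 (cortex), 979 to 1721 (EP), 335 to 1356 (newDC) and 10 to 36 (oldDC), and Cd counts over 6 to 99 (VB), 55 to 1006 (cortex) and 59 to 177 (EP). Between normal tissues they ranged over 6071 to 6814 (VB and cortex), 8796 to 9276 (VB and EP), 6134 to 6909 (EP and cortex) and 4859 to 5411 (newDC and oldDC). Fe differences ranged over 270 to 648, 120 to 311, 297 to 513 and 92 to 408, Cd differences over 1 to 13, 0 to 52 (729 unadjusted without Cd VB replicate 2, limma) and 0 to 40 (1178 unadjusted without normal cortex replicate 1, limma), shared genes over 4 to 39, 28 to 260 and 25 to 73, and list calls over 68 to 75. The lists with a reversed value ranged over -0.0339 to 0.6879 (ribosomal proteins, Fe, cortex) and 0.0220 to 1.063 (histones, Cd, cortex). The Cd difference between VB and cortex was 1, 4 and 13 without Cd cortex replicates 1, 2 and 3, 4 without normal cortex replicate 2, 1, 1 and 4 without Cd VB replicates 1, 2 and 3, and 6 and 8 without normal VB replicates 2 and 3. Between VB and EP it was 7, 12 and 9 without the Cd EP replicates, 2, 8 and 4 without the normal EP replicates, 2, 0 and 52 without the Cd VB replicates, and 2, 6 and 3 without the normal VB replicates. Between EP and cortex it was 3, 10 and 40 without the Cd cortex replicates, 0 and 1 without normal cortex replicates 1 and 3, 36, 19 and 21 without the Cd EP replicates, and 15 and 16 without normal EP replicates 1 and 2.

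On the normal oldDC arrays 46.7% to 53.3% of probes were above background.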

Other observations

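No test in this part was chosen after its result was seen. The adjusted p marked estimated uses an estimated correlation. Jasmonate genes were lower in vascular bundle than in EP (14 of 30, 1 higher, median -1.94, -1.78 at the bound, adjusted p = 0.00424; 0.639 estimated). Glutathione S-transferase genes were higher in EP than in cortex (15 of 35, 3 lower, median 1.11, adjusted p = 0.00408; 0.44 estimated). Under Fe deficiency, ribosomal protein genes rose as a list in the vascular bundle (median 0.38, 0 of 239 called, adjusted p = 2.61e-09; 0.751 estimated) and in the cortex (0.43, 0 of 235, adjusted p = 5.66e-05; 0.837 estimated), the latter lost without Fe-deficient replicate 3 (adjusted p = 0.918). Jasmonate genes fell as a list in Fe-deficient EP (-0.51, 2 of 30 called, adjusted p = 0.00492; 0.641 estimated), lost without normal replicate 3 (0.0793). In Fe-deficient newDC, iron distribution and storage genes fell as a list (-0.21, 3 of 12 called, adjusted p = 0.0432; 0.288 estimated), lost without Fe-deficient replicate 3 (0.18), normal replicate 1 (0.0599) or normal replicate 3 (0.0826).

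Other list calls were lost without 1 array. In the Fe-deficient vascular bundle histones (median 0.46, adjusted p = 0.00734; 0.778 estimated) were not called without Fe-deficient replicate 3 or normal replicate 2. In Fe-deficient oldDC this held for class III peroxidases (-0.33, adjusted p = 0.0108; 0.337 estimated) without any of 3 arrays, for glutathione S-transferases (0.37, 0.17 at the bound, adjusted p = 0.00656; 0.337 estimated) without 1 array, and for phenylpropanoids (0.28, adjusted p = 0.0245; 0.67 estimated) without any of 3. Under Cd it held in the vascular bundle for aquaporins (-0.27, adjusted p = 0.00544; 0.341 estimated) and metallothioneins (0.51, adjusted p = 0.0232; 0.44 estimated), and in the cortex for histones (0.66, adjusted p = 0.00282; 0.751 estimated) and phenylpropanoids (-0.52, adjusted p = 0.021; 0.71 estimated). In Cd-treated EP it held for photosynthesis (0.74, 0.46 at the bound, adjusted p = 0.0163; 0.386 estimated), peroxidases (0.39, 0.30 at the bound, adjusted p = 0.022; 0.523 estimated) and histones (0.38, adjusted p = 0.0234; 0.805 estimated). Photosynthesis genes were higher in newDC than in oldDC (14 of 38, 1 lower, median 1.05, 0.45 at the bound, adjusted p = 0.0294; 0.59 estimated), lost without normal oldDC replicate 1 (0.0588) or 3 (0.0693).

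Of the 510 probes named for microRNAs, 69 were above background on no array, and 13.8% of all their readings were above it.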
